A study of Drosophila melanogaster with 4 samples.

How the data were processed

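The samples were 2 ChIP samples with an antibody against LSD1 and 2 input samples from wild-type Oregon-R embryos of 14 to 16 h. Per the labels' protocols, the embryos were crosslinked with 1.8% formaldehyde, and the chromatin was precipitated with the antibody. Per the labels, each input served the list of 1 ChIP replicate. Groups and replicate numbers were taken from the sample titles.

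Per the submitters' processing notes, Bowtie 0.12.7 was used. The genome was FlyBase release 5, per the file headers. The program that called the regions, its version and its threshold are not given in the sources used here, nor is the way in which the combined list was made. Each deposited list gives a start, an end and a score for every region that the authors called significantly enriched. The unit of this deposited score is not given in the sources used here. Its scale was read from the values: in all 3 lists every score equals the log2 of 1 constant times a ratio of whole numbers, to a relative tolerance of 1e-12 with denominators up to 20000. With natural or base 10 logarithms, between 0.430% and 0.743% of the scores did so. The constant was 2.13 in the combined list, 1.80 in replicate 1 and 2.51 in replicate 2. The score was therefore handled as a log2 value and its fold as 2 to the power of the score. The ratios are in lowest terms, so each whole number is a lower bound of the number it came from. No file states what the whole numbers are, so the depth per sample remains unknown and no interval of a score or fold was built from them. Pairs were compared between lists only where the second number per kb reached 70% of its modal value in the list. Input numbers per kb on X and the autosomal arms were compared over all regions by the 75th percentile, which the reduction to lowest terms lowers less than the median, with 1000 bootstrap draws of regions; this comparison was added after the data were seen. Since the constants differ, scores were compared only within a list, and between lists by rank. Folds of the same region in several lists are given to describe it. The narrowest region was 1001 bp in the combined list and 1301 bp in both replicate lists, and all starts and ends of the combined list are even numbers.

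Positions were used as deposited, counted from 1. Considered were 13 sequences: the 6 arms 2L, 2R, 3L, 3R, 4 and X, and 7 heterochromatic or unplaced sequences. The sequence Uextra, which holds 0 regions, was left out of all lengths. Regions were counted as overlapping when they shared at least 1 bp. Chance was measured with 1000 random circular shifts of the other list within each sequence (one-sided). Medians were compared with two-sided permutation tests of 100000 resamples, and Spearman's rho with the same number. The X density was compared with that of 2L, 2R, 3L and 3R by 1000 rotations of the regions along the joined sequences (two-sided). Adjusted p-values are by Benjamini-Hochberg, with a threshold of 0.05, over 4 tests of shared against single regions and over 3 tests of the score on X. Poisson intervals are exact at 95%. Windows of the length of chromosome 4 were drawn 1000 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

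The named regions follow a rule fixed before the data were examined: the 10 highest-scoring regions of the combined list that both replicates overlap (ties by width, then position), and the widest 5. Other single regions are named as chosen after their values were seen. The alternatives were a stricter score, a larger overlap, lists of equal length, merging of regions closer than 200 bp, restriction to the arms, and either replicate alone. Alternatives added after the data were seen were the minimum width of the replicate lists, minimum whole numbers of 10 and 50, the score correlation on the arms only and among the higher-scoring 50%, and the score on X among the higher-scoring 50% and among regions held by both replicates. Scores of regions in neither replicate list and of regions held by 1 were compared within width classes of 100 bp, with labels permuted within classes 100000 times.

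The procedures were tested on simulated data. Among 2607 regions with 50% placed on the other list, 55.5% overlapped against 11.9% by chance, and with 0% placed there 10.7% overlapped against 11.6% by chance (permutation p = 0.90 with 200 shifts). A planted X density ratio of 1.5 among 9000 regions came back as 1.498. A planted score difference of -0.05 within width classes of 4000 regions came back as -0.049. Whole-number pairs were recovered in 100% of 3000 simulated scores, and found in 0.233% of 3000 scores without them.

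Left out were 4 planned results, namely the share of regions at promoters, their annotation classes, the occupancy of 21 gene lists and the occurrence of 11 motifs. These need a genome sequence and annotation of release 5, which were not used here. The gene table at hand is of release 6, and positions were not converted, so no gene is named. The input samples were not analysed here on their own. A comparison of combined-list scores with percentiles of the replicate scores was computed and is not reported, because each list has its own scale.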

Results

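Chromatin bound by LSD1, a histone demethylase that removes methyl groups from lysine 4 of histone H3, was mapped in wild-type Drosophila melanogaster embryos of the Oregon-R strain at 14 to 16 h of development. The antibody, named Q3430 in the labels, was used for immunoprecipitation of formaldehyde-crosslinked chromatin, followed by sequencing (ChIP-seq). The series held 2 ChIP samples and 2 input samples, the latter being genomic DNA that served as background, 1 for each ChIP. Results were 3 lists of enriched regions, 1 for each ChIP replicate and 1 combined list for the replicate set. The read depth per sample is unknown, since the lists give positions and 1 score per region only. The score was deposited by the authors, and its values lie on a log2 scale, so enrichment is given below as the fold that the score corresponds to. Folds describe and rank regions within a list. Nothing in the labels says that the replicates came from separate embryo collections, so the p-values speak of the placement or the values of regions in these libraries, and the spread between the replicates may be technical.

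LSD1 enrichment was widespread and mostly shallow. The combined list held 9018 regions covering 19.0 Mb, or 13.6% of the 139.7 Mb of sequence considered. Of these regions, 52.1% overlapped no region of either replicate list, and they made up 34.5% of the covered bases. Replicate 1 had 3951 regions over 9.29 Mb and replicate 2 had 2607 regions over 5.24 Mb. The median width was 1655 bp in the combined list, 1972 bp in replicate 1 and 1893 bp in replicate 2. The median region was enriched 1.35-fold in the combined list, 1.55-fold in replicate 1 and 1.55-fold in replicate 2, each on the scale of its own list. Enrichment above 2-fold was found at 411 regions (4.56%) of the combined list, 380 regions (9.62%) of replicate 1 and 397 regions (15.2%) of replicate 2. Above 4-fold there were 109, 79 and 110 regions. These are single values per list and were not tested.

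The strongest regions that both replicates held lay on 5 sequences. The highest was at 2R:19954850-19957756 (release 5 of the fly genome, as are all positions here), 2907 bp wide and enriched 13.3-fold in the combined list, 12.03-fold in replicate 1 and 15.0-fold in replicate 2. Second was X:17615802-17618358, at 12.4-fold, 11.5-fold and 14.6-fold in the same order. After it came 3L:6392274-6394874, at 12.015-fold, 10.9-fold and 13.8-fold. The next was 2R:19518704-19521214 at 9.67-fold in the combined list. A heterochromatic sequence followed, 2RHet:2283050-2286014, at 8.95-fold in the combined list, 8.94-fold in replicate 1 and 10.6-fold in replicate 2. The remaining regions of the highest 10 were 3R:15287642-15291148 (7.85-fold), 3L:16153710-16159032 (7.57-fold), 3R:19138880-19142306 (7.47-fold), 3L:18613440-18616960 (7.12-fold) and 3L:14571042-14573438 (6.98-fold). Each of these 10 regions met exactly 1 region in each replicate list, and that region ranked 23 or higher there. Their replicate regions covered between 72.1% and 100% of the combined region in replicate 1 and between 74.4% and 99.8% in replicate 2. No annotation of release 5 was used here, so no gene is named at any position.

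Broad domains formed a small part of the binding. The combined list held 65 regions wider than 10 kb, 956 kb in all or 5.03% of its covered bases, with a median enrichment of 1.58-fold. Both replicates held 60 of them, and the other 5 were held by 1 replicate. They lay on 3R (19), 2R (15), 3L (12), 2L (10) and X (9), with 0 on chromosome 4. The widest spanned 33.8 kb at X:1148400-1182214 and was enriched 2.76-fold. Within it, replicate 1 called 6 regions and replicate 2 called 5, covering 80.2% and 53.5% of its length. Its strongest part was X:1161222-1172750 in replicate 1, at 4.37-fold, and X:1163145-1172384 in replicate 2, at 6.78-fold. The next widest were 3R:12056386-12084162 (27.8 kb, 1.82-fold), 3L:624052-650100 (26.0 kb, 1.60-fold), 2R:5428894-5454824 (25.9 kb, 1.78-fold) and 3R:5693444-5719296 (25.9 kb, 1.60-fold). For 3L:624052-650100 the replicates differed in extent, with 92.7% of its length covered in replicate 1 and 33.1% in replicate 2.

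Whether the replicates marked the same places was asked by overlap. Of the 2607 regions of replicate 2, 1789 (68.6%) shared at least 1 bp with a region of replicate 1. Circular shifts of the regions within each sequence gave 12.9% on average. In the other direction, 1725 of 3951 regions of replicate 1 (43.7%) were held by replicate 2, against 8.77% by chance. Both shares lay above all 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Together the replicates covered 10.98 Mb, of which 3.55 Mb (32.4%) was covered by both. The share of shared regions is tied to the different lengths of the lists: among the 2607 highest-scoring regions of each, 52.6% of those of replicate 2 and 49.4% of those of replicate 1 were shared. Strong enrichment was shared almost completely, with 368 of the 380 regions above 2-fold in replicate 1 (96.8%) and 393 of the 397 in replicate 2 (99.0%) held by the other replicate. The highest score of replicate 1 was an exception, singled out after its value was seen. The region 3R:17129511-17130967 scored 16.2-fold, a ratio that reduces to 9 to 1 in lowest terms, and neither replicate 2 nor the combined list had a region there.

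Regions found in both replicates were wider and more enriched than those found in 1. In replicate 1 the median width was 2195 bp for 1725 shared regions and 1694 bp for 2226 single ones, a difference of 501 bp. In replicate 2 it was 2041 bp for 1789 shared and 1512 bp for 818 single regions, a difference of 529 bp. Median enrichment was 1.62-fold against 1.52-fold in replicate 1, a score difference of 0.09, and 1.59-fold against 1.51-fold in replicate 2, a score difference of 0.07. All 4 differences were past the threshold (two-sided permutation tests with 100000 resamples, adjusted p = 1e-05 each by Benjamini-Hochberg over 4 tests, the smallest they can give). Above 2-fold were 21.3% of the shared and 0.539% of the single regions in replicate 1, and 22.0% and 0.489% in replicate 2. A wider region also meets another by chance more often, so the width difference is not independent of the overlap. Wider regions also scored higher (Spearman's rho 0.588 in replicate 1 and 0.603 in replicate 2), so the score difference may follow from width. Scores of shared and single regions were not compared at matched width.

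The combined list held nearly all replicate regions and many more. It overlapped 3853 of the 3951 regions of replicate 1 (97.52%; 28.1% by shifts) and 2527 of the 2607 of replicate 2 (96.9%; 26.6% by shifts). Conversely, 4318 of its 9018 regions (47.9%) were held by at least 1 replicate list, against 15.5% by chance (one-sided permutation p = 0.001 for each of the 3 shares, the smallest these shifts can give). The combined list belongs to the replicate set of the same ChIP samples, so overlap above shifts was to be foreseen. These p-values therefore say nothing about reproducibility. Both replicates held 1649 regions (18.3%), replicate 1 alone 1965 (21.8%), replicate 2 alone 704 (7.81%) and neither 4700 (52.1%). The share of 47.9% depends on which replicate is kept: it was 40.1% with replicate 1 alone and 26.1% with replicate 2 alone, the latter against 8.25% by chance.

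Support in the replicates followed the width, and the score mainly in the upper part of the list. Among the highest-scoring 10% of the combined list, 81.1% of regions were held by both replicates and 84.5% by at least 1. In the second group of 10% they were 41.6% and 64.4%, and in the next 19.5% and 46.2%. From there on the share held by at least 1 was flat, between 38.7% and 41.6% in each group, while the share held by both ended at 3.44% in the lowest. The highest 2 groups were also wider, with median widths of 2563 and 2162 bp. Regions narrower than 1301 bp, the smallest width in either replicate list, were held by a replicate in 10.3% of 2787 cases, against 12.7% by shifts. The 6231 regions of at least that width were held in 64.7% of cases, against 16.7% by shifts. The share was 42.3% for widths from 1301 bp up to 2000 bp and 85.2% from 2000 to 3000 bp. It was 94.3% from 3000 to 5000 bp and 99.5% for the 425 regions of 5000 bp or more. Wider regions also meet a replicate region by chance more often, and no shifts were run within these width groups. Regions in neither list had a median width of 1269 bp and a median enrichment of 1.34-fold. Those held by both had 2859 bp and 1.497-fold, and those held by replicate 1 alone 1979 bp and 1.34-fold.

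**Figure D1:**
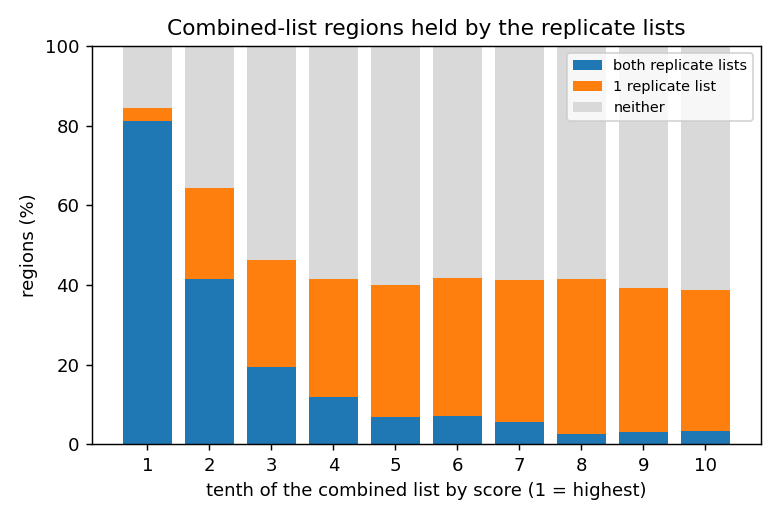
Share of combined-list regions (vertical axis, percent) held by both replicate lists, by 1 or by neither, in equal groups of regions ordered by score (horizontal axis, 1 is the highest-scoring 10%). The share held by both fell from 81.1% in group 1 to 3.44% in group 10.

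The strength of LSD1 enrichment ranked regions alike in both replicates. Across the 1649 combined-list regions held by both, Spearman's rho of the replicate scores was 0.725 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The correlation is across regions, which are not independent replicates, and it uses only ranks because the lists were called separately. Wider regions scored higher in each replicate list (Spearman's rho 0.588 in replicate 1 and 0.603 in replicate 2). The shared ranking may therefore follow width in part, and it was not examined at matched width.

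**Figure D2:**
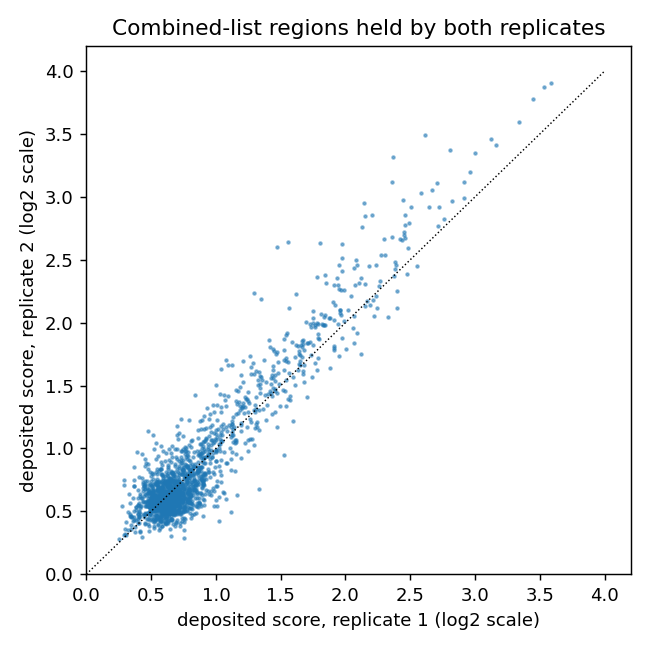
Deposited score in replicate 1 (horizontal axis, log2 scale) and in replicate 2 (vertical axis, log2 scale) for the 1649 combined-list regions held by both, each point 1 region with the highest score that overlaps it in each list, and a dotted line where the scores are equal. Most points lie in a dense group near the median enrichment, and a tail reaches up to the strongest shared regions (Spearman's rho 0.725).

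LSD1 regions were spread over all large chromosome arms, with fewer on chromosome 4 and on heterochromatic or unplaced sequence. In the combined list 2R had the highest density, at 84.6 regions per Mb (95% exact Poisson interval 80.7 to 88.6), with 18.7% of its bases covered. Densities were 73.8 per Mb on 3L (70.5 to 77.3), 72.1 on 3R (68.95 to 75.3), 70.3 on 2L (66.9 to 73.8) and 69.4 on X (66.0 to 73.0). The arm 2R was also the densest in each replicate, at 39.8 per Mb in replicate 1 and 26.3 in replicate 2. Chromosome 4 had 45.1 per Mb (34.5 to 58.0). Its 61 regions compare with a median of 102 in 1000 windows of the same length drawn from the 5 large arms, and 5.30% of these windows held as few. In replicate 1 that share was 8.90%, for 26 regions, and in replicate 2 it was 13.2%, for 19 regions, so the lower count on chromosome 4 was within the spread of such windows. The intervals cover counting error only, and neighbouring regions are not independent.

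**Figure D3:**
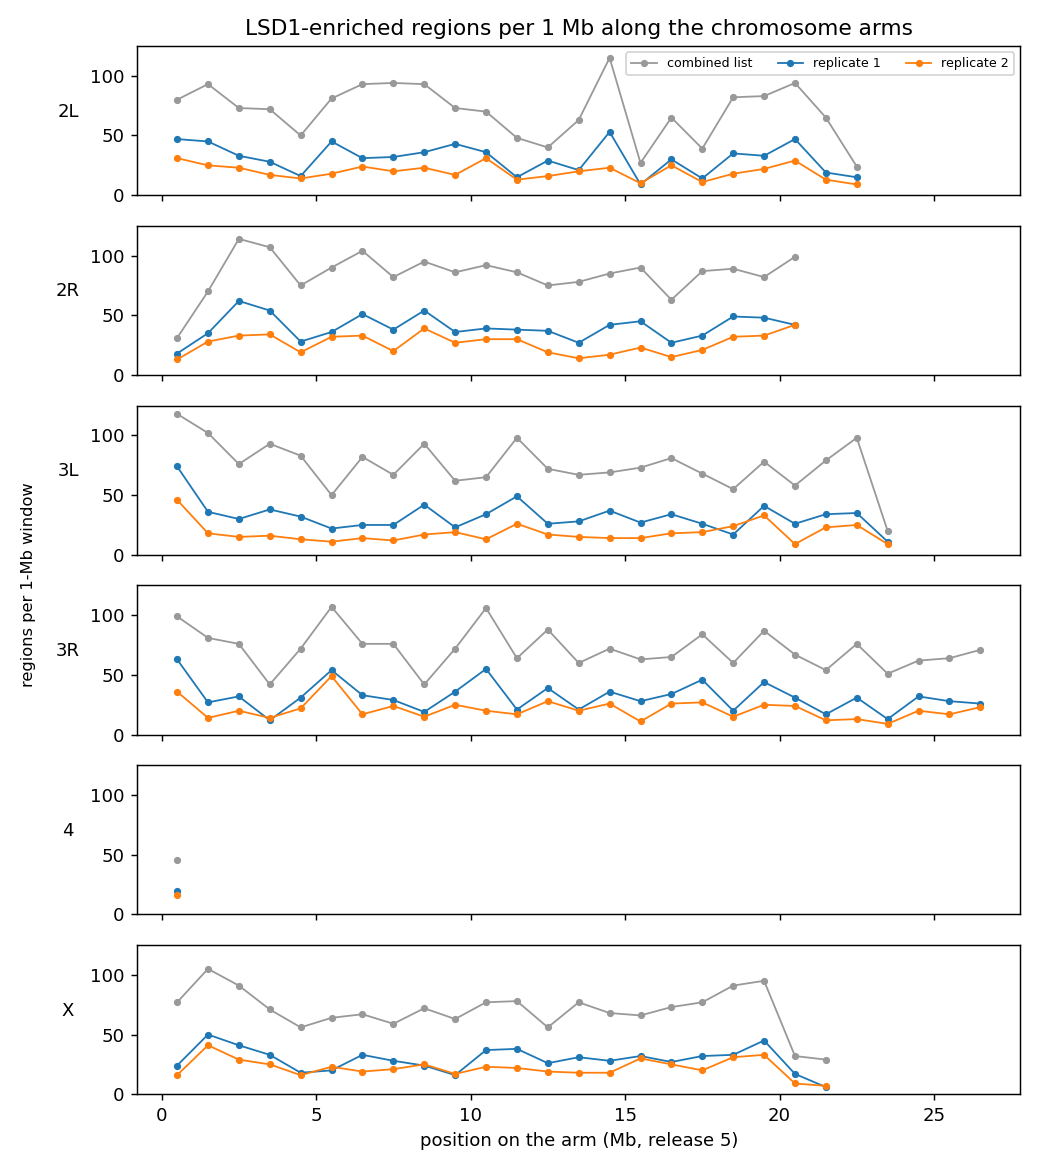
Number of LSD1-enriched regions in windows of 1 Mb (vertical axis) along each chromosome arm (horizontal axis, position in Mb) for the combined list, replicate 1 and replicate 2. The last incomplete window of each arm is left out. The combined list ranges from 20 to 118 regions per window with a median of 75.

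Along the arms, the window with most combined-list regions was 3L:1-1000000, at the end of the arm away from the centromere, with 118 against a median of 75 over 118 windows. It also had the most regions in replicate 1, with 74. In replicate 2 the densest window was 3R:5000001-6000000, with 49. The window with fewest regions in both replicates was X:21000001-22000000, with 6 in replicate 1 and 7 in replicate 2.

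The X chromosome, of which males carry 1 copy, did not differ detectably from the autosomal arms in region density. The ratio of X to autosomal density was 0.928 in the combined list (two-sided permutation p = 0.685 over 1000 rotations, which by themselves gave ratios from 0.516 to 1.32). The rotated sequences include the heterochromatic and unplaced ones, with 8.90 regions per Mb against 73.5 on the 6 arms. Rotations move these sparse stretches onto X or the autosomal arms, which may widen that range. A ratio inside the range cannot be told from 1, so equal density is not shown. The ratio was tested in each replicate too. It was 0.861 in replicate 1 (permutation p = 0.468) and 1.03 in replicate 2 (permutation p = 0.894), so the replicates lay on different sides of 1. The ratio of 1.53 among the higher-scoring 50% of the combined list (permutation p = 0.0879) restates a difference in score, since 1139 of 1557 X regions and 3216 of 7228 autosomal regions are in that part. Regions on X had higher scores. Their median was 1.40-fold against 1.35-fold on the autosomal arms in the combined list, 1.62-fold against 1.53-fold in replicate 1 and 1.63-fold against 1.53-fold in replicate 2. The differences in median score were 0.06, 0.08 and 0.09. This comparison was added after the data were seen, and all 3 differences were past the threshold (two-sided permutation tests, adjusted p = 1e-05 each over 3 tests, the smallest they can give). The tests of scores on X permute single regions, although neighbouring regions are not independent and there is only 1 X. Their p-values therefore do not measure the spread between chromosomes. Among regions held by both replicates, the medians were 1.728-fold against 1.59-fold in replicate 1 and 1.69-fold against 1.57-fold in replicate 2 (permutation p = 1e-05 each, the smallest possible). Among the higher-scoring 50% of replicate 2, a selection on the compared score itself, the medians were 1.70-fold on X and 1.71-fold on the autosomal arms (permutation p = 0.735). If the whole numbers behind the scores are reads, input depth was lower on X. The upper quartile of the input number per kb was 97.1 on X and 129.5 on the autosomal arms in replicate 1 (ratio 0.75, 95% bootstrap range 0.735 to 0.764), and 113.4 and 154.3 in replicate 2 (ratio 0.735, 0.719 to 0.757).

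Sequence outside the arms, meaning the heterochromatic sequences and the unplaced sequence U, held few regions, and those on U scored highest. The combined list had 172 regions there, or 8.90 per Mb over 19.3 Mb, against 73.5 per Mb on the 6 arms. The 87 regions on U had a median of 2.43-fold, against 1.35-fold on the arms. Medians were also higher on YHet (1.99-fold, 3 regions), 2RHet (1.60-fold, 28 regions) and 3RHet (1.43-fold, 22 regions), but lower than on the arms on XHet (1.32-fold, 6 regions), 3LHet (1.317-fold, 21 regions) and 2LHet (1.2965-fold, 5 regions). In the replicate lists 3LHet and 2LHet lay above the 1.55-fold of the arms instead, at 1.69-fold (12 regions) and 2.69-fold (2 regions) in replicate 1 and at 2.29-fold (7 regions) and 2.87-fold (2 regions) in replicate 2. Outside the arms 79 regions exceeded 2-fold, of which both replicates held 30, while on the arms 332 did and both held 294. Among regions held by both, 58.8% of 51 outside the arms and 18.4% of 1598 on the arms exceeded 2-fold, with medians of 2.44-fold and 1.495-fold. Of the 25 regions among the 50 highest scores that neither replicate held, 16 lay outside the arms. How much of this sequence short reads can reach is unknown here, so the densities do not compare the binding itself, and these differences were not tested.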

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

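The tests on minimum widths, minimum whole numbers, scores on X, and the correlation on the arms or among the higher-scoring 50% were chosen after the results were seen. Of 55 alternatives to 17 results, 49 kept direction, side of the threshold or, for list lengths, a value within 1.5 times. Some of the 49 could hardly change. The minimum width of 1301 bp leaves both replicate lists as they are, and overlap of the combined list with the replicates was to be foreseen. The overlap of the replicates stayed above chance under each overlap rule and list restriction run, from 52.6% to 68.3% of replicate 2 and from 35.8% to 49.4% of replicate 1. Spearman's rho ranged from 0.711 to 0.813. The upper 50% of each list has 4509, 1975 and 1303 regions, lower by construction. The X density ratio turned from 0.928 to 1.53 in the upper 50% of the combined list (permutation p = 0.0879), by construction, as a larger share of X than of autosomal regions scores that high, and ranged from 0.861 to 1.03 with either replicate alone, for which the cause was not tested. The X minus autosome score in replicate 2 turned to -0.0085 in its upper 50%, a selection on the score compared itself, and stayed at 0.11 among regions held by both replicates. The combined-list share held ranged from 26.1% to 40.1% with either replicate alone, where only 1 list can hold a region, and was 64.7% for widths of at least 1301 bp. No paired analysis was possible because the inputs have no lists of their own, so no groups sharing replicate numbers could be compared. The alternatives for promoters, annotation classes, gene lists and motifs were not run, for want of a release 5 annotation and sequence. Depth per sample is unknown, so a region absent from a list was not detected there rather than shown to be unbound.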

Other observations

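The tests of high scores, of pooled reads and of regions in neither replicate list, except the share narrower than any replicate region, were chosen after the results were seen, as was the comparison of scores on X itself.

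LSD1 regions lay closer together than random placement gives. On the arms, the median distance from 1 region to the next was 4.26 kb in the combined list, while 1000 random placements of the same widths gave 7.59 to 8.19 kb. Replicate 1 showed 8.97 kb (at random 18.5 to 20.6 kb) and replicate 2 showed 22.6 kb (28.4 to 33.5 kb). For regions held by both replicates it was 35.3 kb (43.5 to 53.0 kb). Of these, 16.9% of the distances were under 5 kb, against 6.82% at random. The placements keep neither unmappable stretches nor gene density, so regions may cluster because the sequence that can hold them does, which the 4.26 kb cannot exclude. The distances are between regions as deposited. Merging of those closer than 200 bp left 8461 of the 9018 combined-list regions and 3781 of the 3951 of replicate 1. Some short distances may therefore lie within 1 enriched domain.

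Whether regions thin out towards the centromere was asked in the 2 Mb at the centromere end of the sequence of 5 arms. The heterochromatic sequences are listed apart from the arms and are not part of these windows. Density there was lower than in the rest of the arm on X (28.5 against 73.4 per Mb), 3L (30.5 against 77.7), 2R (50.5 against 88.1) and 2L (42.0 against 73.0). On 3R it was higher, at 90 against 70.7 per Mb. Each replicate list showed lower density on the same 4 arms and higher density on 3R. The mean log2 ratio over arms in the combined list was -0.79 (SD 0.70, n = 5 arms, exact sign-flip permutation p = 0.125, where the smallest possible is 0.0625). Lower density in this part of all 5 arm sequences is therefore excluded by 3R in these lists. The windows cannot say what holds in heterochromatic sequence. There 3RHet had 8.74 regions per Mb in the combined list, and its reach by short reads is unknown.

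Of the 50 highest scores of the combined list, 25 belong to regions that neither replicate list holds, among them the highest of all, U:7289244-7290244, at 14.9-fold and the minimum width of 1001 bp (singled out after its value was seen). If the whole numbers behind the scores are reads, few reads in the window may account for them: the smaller number of the pair, a lower bound because ratios are in lowest terms, had a median of 1 in these 25 regions and of 429 in the 1649 regions held by both. It was 10 or less in 25 of the 25 and in 19 of the 1649 (1.15%), so reduction to lowest terms seldom gives such low numbers where both replicates hold a region. Unplaced and heterochromatic sequence held 16 of the 25 (64.0%, exact 95% interval 42.5% to 82.0%), against 1.91% of the whole list, and the interval leaves open whether most such regions lie there. No biological explanation was tested.

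The 4700 combined-list regions in neither replicate list were mostly narrow: 53.2% were narrower than any replicate region, between the over 90% and the at most 50% set beforehand as deciding for or against a shorter minimum width as the whole cause. A replicate held 10.3% of the 2787 regions under 1301 bp, below the 12.7% that shifts gave. This cannot decide for that minimum. Nearly all replicate regions, none narrower than 1301 bp, lie on combined-list regions, so a low share on the narrow ones was likely whatever the cause. The minimum also leaves the other 2200 (46.8%), of which 1902 lie under 2000 bp, so width itself stays open. Weaker enrichment stays undecided for these 1902. Their median score within width classes of 100 bp was 0.0060 above that of 1283 regions held by 1 replicate (permutation p = 0.0363). That comparison left out the 112 regions of this width that both replicates held. It also used the score of the combined list, not that of either replicate. Weaker enrichment remains a candidate explanation for the 298 regions of 2000 bp or more, at -0.033 against 1101 (permutation p = 1e-05, the smallest possible). Without matching on width the difference over all 2200 was -0.022. Pooling of both replicates' reads is consistent with the number pairs, as the combined numbers were 1.01 (ChIP) and 1.03 (input) times the sums over replicates in 70 regions with bounds within 150 bp.

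Higher scores on X than on the autosomal arms were weighed against sequencing depth. The difference did not rest only on regions with low whole numbers, since it stayed among those whose smaller whole number is at least 50. Among them the difference in median score was 0.081 in replicate 1 and 0.095 in replicate 2 (permutation p = 1e-05 each, the smallest possible, with single regions permuted). This cut also drops pairs that reduce to small numbers, and it does not equalise depth between X and the autosomal arms. It therefore cannot decide whether lower depth on X raised the scores. Input numbers per kb on X were 0.75 of the autosomal ones in replicate 1 and 0.735 in replicate 2, and fewer reads, which would raise the score needed for a call, would shift low scores at least as much as high ones. The difference at the 90th percentile minus that at the 10th was 0.13 in replicate 1 (95% bootstrap range 0.03 to 0.32) and -0.058 in replicate 2 (-0.26 to 0.27), so this cannot be told apart from stronger enrichment on X, as the replicates go opposite ways and the range in replicate 2 includes 0.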
